A study of Mus musculus with 16 samples.

How the data were processed

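RNA of whole retina from 16 C57BL/6 mouse samples, 4 per sex and age, was measured on 1-colour Illumina BeadChips. Per the labels' protocols the mice were left untreated, RNA was extracted with Trizol and cleaned on RNeasy columns with DNase I, its quality was checked on a Bioanalyser, and biotinylated cRNA was made with a TotalPrep kit. Groups were read from the sample titles and the sex and age labels, and slides from the array names in the labels.

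The deposited table of probe intensity values is an export of the array software, per the file headers, with 1 average signal per probe and array. Between 20.7% and 24.2% of the values per array lay below 0, so a background value had been subtracted, while the array means differed, so the arrays had not been scaled to each other. The detection p-value beside each signal was deposited by the authors and came, per the file headers, from the same export, and its steps stand for 798 negative control probes. A second deposited table held the same intensities multiplied by 1 factor per array (0.821 to 1.25), which gave every array a mean of 197 and medians of 10.5 to 13.2. It was on a linear scale, not centred by gene and with no direction to settle. The software, its version and the build behind the probe annotation are not given in the sources used here, so no coordinates are given.

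Probes were named by the symbol in their annotation, updated through the symbols and unique synonyms of a table of RefSeq genes, which matched 24761 of 25697 probes. The other 936 kept their name in the file. Of 17087 symbols 4909 had more than 1 probe, and a gene is given by its brightest tested probe (highest mean over the 16 arrays), with a remark where other probes of a named gene had the opposite sign.

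Intensities were corrected for background and normalised with neqc of limma 3.58.1 in R 4.3.3 (normexp with negative controls inferred from the detection p-values, offset 16, quantile normalisation, log2), with statmod 1.5.0 for correlations within slides. Probes with a detection p-value under 0.05 on at least 4 of the 16 arrays were tested. A single limma model (lmFit, eBayes) with a mean for each of the 4 groups and 12 residual degrees of freedom gave aging in each sex, the mean of both, the sex difference at each age and the interaction, two-sided, with Benjamini-Hochberg adjustment per comparison and a threshold of 0.05. The arrays of a group correlated at 0.983 to 0.995, and none was a copy of another. Overlaps of calls were tested with Fisher's exact test.

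Gene lists were tested with camera in limma (preset correlation 0.01, lists of at least 5 measured genes, adjusted over the lists), and again with an estimated correlation and with the rotation test fry. The 34 lists held markers of rods, cones, bipolar, amacrine and horizontal cells, ganglion cells, Müller glia, microglia, endothelium, pigment epithelium, lens, skeletal muscle, blood, lymphocytes and fibroblasts. They also held genes of complement, MHC class I and II, interferon response, cytokines, gliosis, senescence, oxidative phosphorylation, ribosome, proteasome, antioxidant defence, unfolded protein response, immediate early response, circadian clock, synapse, cholesterol, visual cycle, basement membrane, sex steroids and X-escape with Y-linked genes. Some genes stand in more than 1 list. For each comparison the named genes are the 10 largest changes upward and the 10 downward among called probes, 1 probe per gene, and where fewer than 5 passed also the 5 with the smallest p. To these were added, per list, up to 4 members with the smallest p, all Y-linked and X-escape genes, Gfap and the complement genes. A gene that this rule takes is not reported here. Groups, comparisons, lists, this naming rule and the alternatives were fixed before the data were examined, except the count of autosomal probes called for sex at both ages.

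Alternatives were no background correction, median scaling, the authors' scaled values, no filter or a stricter one (detection p-value under 0.01 on all 16 arrays), 1 probe per gene, an intensity trend with robust variances, array weights and slide as a fixed or random block. Further ones were slide 1 against the others, the replicate number as a block, only the 2 groups compared, an unadjusted p under 0.05 with a fold of 1.2, and each array left out in turn. Slide-blocked and within-slide values are given as slides 1 to 4 held over 1 group each. Scripts were tested on simulated changes of log2 0.5, 1, 1.5 and 2 in 50 probes each. For aging in females 84, 96, 98 and 100% of them were recovered with 7 false calls among 15016 probes, for the mean of both sexes 82, 98, 98 and 100% with 6, and for the interaction 28, 88, 98 and 98% with 13. Camera called both shifted simulated lists and 0 of 30 others. These runs test scripts, not false calls or power in real data.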

Results

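The series measured RNA of whole retina from C57BL/6 mice, a common inbred laboratory strain, on single-colour Illumina BeadChips, which read each probe as the brightness of labelled complementary RNA bound to beads. Females and males were each sampled young, at 3 months, and aged, at 24 months, with 4 arrays in each of the 4 groups. The labels of male aged 1 disagree on its age, with aged in the title and 12 months in the age field, and the array was kept in the aged group. The arrays lay on 5 slides, all but 1 of which carried more than 1 group. Mean intensity per array ran from 158 to 240, and 52.6% to 57.0% of the 25697 probes had a detection p-value under 0.05. The 15016 probes tested stood for 11035 named genes. The number of arrays, 4 per group, limits the precision of each value. The labels do not say that the arrays came from separate animals, so the p-values measure the spread between these samples, part of which may be technical. Levels are log2 normalised intensities given as mean ± SD over 4 arrays, changes are log2 differences with the standard error (SE) of limma's model, and adjusted p-values are limma's after Benjamini-Hochberg correction over all probes tested. Where a gene lay below detection on every array of the dimmer group, the change is given as a bound (at least N-fold), the brighter group's mean over the dimmer group's mean of the lowest detected signals.

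The first comparison asked how the retina of females differed between 3 and 24 months. Ccl21b, Ccl21c and Ccl21a, near-identical copies of a chemokine gene, had log2 changes of 2.29 (SE 0.27), 1.78 (SE 0.22) and 1.73 (SE 0.19). Their probes may not fully separate them, which was not checked by sequence. Ccl21b rose 4.90-fold from 5.02 ± 0.82 to 7.31 ± 0.23 (n = 4 each, limma adjusted p = 0.000227). Edn2, which encodes the peptide endothelin 2, rose 4.06-fold from 7.08 ± 0.39 to 9.10 ± 0.60 (2.02, SE 0.33, adjusted p = 0.00479). Csrp3, a LIM protein gene best known from striated muscle, rose 3.05-fold (1.61, SE 0.15, adjusted p = 5.29e-05), with all 3 of its probes called. Agtr1a, the receptor gene of angiotensin II, was at least 2.42-fold higher in aged females (4.30 ± 0.06 in young and 5.87 ± 0.29 in aged, adjusted p = 5.29e-05). In all 80 probes (70 genes) rose and 15 (14 genes) fell. An unadjusted p under 0.05 was found for 1072, where chance gives 750.8. The other genes among the 10 largest rises were Trf, the iron carrier transferrin (1.53, SE 0.22, adjusted p = 0.00161) and Rdh9 of the retinol dehydrogenase family (1.37, SE 0.15, adjusted p = 0.000139). They were followed by the acidic chitinase Chia1 (1.27, SE 0.26, adjusted p = 0.0267) and Pglyrp1, a peptidoglycan recognition protein (1.11, SE 0.22, adjusted p = 0.0245). The largest falls were those of 1110017D15Rik (-1.87, SE 0.38, adjusted p = 0.0284) and the crystallin gene Crygn (-1.58, SE 0.31, adjusted p = 0.0212). Dynlrb2, a light chain of the dynein motor, was at least 1.70-fold lower (5.36 ± 0.35 in young and 4.25 ± 0.05 in aged, adjusted p = 0.000227). Mid1 (-1.03), Aldh1a7 (-0.91), the growth factor receptor gene Pdgfra (-0.82), Nxnl2 (-0.64), Bmp15 (-0.63), Shisa2 (-0.62) and Chrnb1 (-0.59) fell too. These 7 had SEs of 0.08 to 0.20 and adjusted p-values of 0.00043 to 0.0390. All 95 called probes kept their sign within slides 2 and 4, each with 1 female array per age. Such counts, here and below, reuse the calling arrays and test little. The named rises ran from 0.47 (Chia1) to 2.35 (Trf) on slide 2 and from 1.14 (Pglyrp1) to 3.25 (Ccl21b) on slide 4. A slide block left 64 called probes, and the same rises ran from 1.06 (Chia1) to 2.44 (Ccl21b). It ended the calls of Chia1 (1.06, adjusted p = 0.137), Pglyrp1 (1.31, adjusted p = 0.0537), 1110017D15Rik (-1.53, adjusted p = 0.165), Mid1 (-0.94, adjusted p = 0.182) and Chrnb1 (-0.59, adjusted p = 0.0613). Without female young 1 the 95 calls became 59. Leaving out female young 1, 2, 3 or 4, female aged 1, 2, 3 or 4, male young 2 or 3 or male aged 1, 3 or 4 ended at least 1 of the calls named next. These were Chia1 (adjusted p up to 0.10), Pglyrp1 (up to 0.0975), 1110017D15Rik (up to 0.102) and Crygn (up to 0.0624). Next came Mid1 (up to 0.0909), Aldh1a7 (up to 0.139), Pdgfra (up to 0.114), Shisa2 (up to 0.0690) and Chrnb1 (up to 0.138).

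Gene lists of immune cells and immune responses were called upward in aged females. All 21 measured markers of microglia and macrophages, the phagocytes of the retina, lay above 0 and 4 rose (12 adjusted over the list alone). The microglia list had a median log2 change of 0.38 (adjusted p = 3.39e-20, and adjusted p = 0.00315 with an estimated correlation). The 4 were Ly86 (0.75, SE 0.08, adjusted p = 0.000139), the fractalkine receptor gene Cx3cr1 (0.56, SE 0.08, adjusted p = 0.00142), the lipopolysaccharide receptor gene Cd14 (0.74, SE 0.13) and Cd52 (0.39, SE 0.09). Of the interferon response genes 6 of 30 rose (21 adjusted over the list alone). The interferon list had a median log2 change of 0.44 (adjusted p = 4.19e-26, and adjusted p = 0.00315 with an estimated correlation). The risen genes included Parp14 (0.67, SE 0.11, adjusted p = 0.00388), the guanylate-binding protein gene Gbp2 (0.92, SE 0.17, adjusted p = 0.0123), Oasl2 (0.97, SE 0.17) and Trim30a, at least 1.43-fold higher. Of the complement genes 3 of 13 rose (6 adjusted over the list alone), the C1q subunit genes C1qc (0.94, SE 0.18), C1qb (0.93, SE 0.19) and C1qa (0.71, SE 0.15). The complement list had a median log2 change of 0.25 (adjusted p = 2.19e-06, and adjusted p = 0.0756 with an estimated correlation). C3, the central complement component (0.54, SE 0.15, adjusted p = 0.201), and C4b (1.01, SE 0.29, adjusted p = 0.207) did not pass the threshold. Of the MHC class I genes 1 of 17 rose (4 adjusted over the list alone), H2-T23 (0.53, SE 0.09, adjusted p = 0.0122). The MHC class I list had a median log2 change of 0.071 (adjusted p = 0.000191, and adjusted p = 0.236 with an estimated correlation). Of the cytokine and inflammasome genes 1 of 15 rose (3 adjusted over the list alone), the chemokine gene Ccl12 (0.74, SE 0.12, adjusted p = 0.00479). The cytokine list had a median log2 change of 0.11 (adjusted p = 0.00161, and adjusted p = 0.267 with an estimated correlation). Of the reactive gliosis genes, markers of the response of glia to injury, 4 of 18 rose and 0 fell (6 and 1 adjusted over the list alone), Edn2, Gbp2, the oncostatin M receptor gene Osmr (0.71, SE 0.11, adjusted p = 0.00266) and the lipocalin gene Lcn2 (1.05, SE 0.23). The gliosis list had a median log2 change of 0.12 (adjusted p = 0.000674, and adjusted p = 0.277 with an estimated correlation). Gfap, the intermediate filament gene of glia, lay near background and did not pass (0.05, SE 0.09, adjusted p = 0.959). The 3 measured blood genes, too few to test, all lay above 0 with a median of 1.17 (2.06 within slide 2 and 0.41 within slide 4). With the slide as a block (adjusted p in brackets), within slide 2 and within slide 4, the medians were as follows. They were 0.44 (2.74e-18), 0.61 and 0.22 for microglia, 0.48 (2.54e-27), 0.69 and 0.49 for interferon response and 0.42 (1.65e-08), 0.72 and 0.25 for complement. The next were 0.19 (6.98e-07), 0.40 and 0.058 for MHC class I, 0.12 (0.00222), 0.38 and 0.011 for cytokines and 0.19 (0.000483), 0.43 and 0.18 for gliosis. For single genes it ended those of Cd14 (0.62, adjusted p = 0.0726), Gbp2 (0.98, adjusted p = 0.0756), Oasl2 (0.99, adjusted p = 0.0683), Trim30a (0.62, adjusted p = 0.142), C1qa (0.69, adjusted p = 0.226) and Lcn2 (1.05, adjusted p = 0.158). The removal of female young 1, 2, 3 or 4, female aged 1, 2 or 3, male young 1, 2, 3 or 4 or male aged 1, 2, 3 or 4 ended at least 1 of the calls named next. These were Cd52 (adjusted p up to 0.191), Gbp2 (0.0514), Trim30a (up to 0.0654) and C1qc (up to 0.0647). Next came C1qb (up to 0.104), C1qa (up to 0.125) and Lcn2 (up to 0.192).

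Other lists were called in females too, and none of these calls held with an estimated correlation. Upward were bipolar cells, the interneurons behind the photoreceptors (median 0.15, adjusted p = 0.00212), endothelium and mural cells (median 0.079, adjusted p = 0.0128), the visual cycle, which regenerates the light-sensing chromophore (median 0.092, adjusted p = 0.00109), and the unfolded protein response with heat shock (median 0.052, adjusted p = 0.0482), at adjusted p = 0.301, 0.277, 0.236 and 0.277 with an estimated correlation in that order. Called members were 0 of 16, 1 of 17, 0 of 16 and 1 of 27 (0, 4, 6 and 1 adjusted over the list alone), the surface antigen gene Ly6a for endothelium (0.87, SE 0.19, adjusted p = 0.0457) and the stress-induced transcription factor gene Atf3 for the unfolded protein response (0.65, SE 0.10, adjusted p = 0.00230). Downward were lens genes with crystallins (median -0.80, adjusted p = 4.01e-09), basement membrane with vascular matrix (median -0.15, adjusted p = 0.00960) and fibroblasts with extracellular matrix (median -0.087, adjusted p = 0.0432), at adjusted p = 0.267, 0.405 and 0.514 with an estimated correlation. Of the lens genes 1 of 17 fell, Crygn (3 adjusted over the list alone), and of the fibroblast genes 1 of 14, Pdgfra (1 adjusted over the list alone). In the basement membrane list 0 of 18 fell (4 adjusted over the list alone) and 1 rose, the type IV collagen chain gene Col4a3 (0.90, SE 0.17, adjusted p = 0.0145). Downward with 0 called members, also adjusted over the list alone, were ganglion cells (13 measured, median -0.094, adjusted p = 0.0159), oxidative phosphorylation (82, median -0.031, adjusted p = 0.0198), antioxidant defence with metallothioneins (32, median -0.050, adjusted p = 0.0432) and cholesterol synthesis with lipid transport (26, median -0.058, adjusted p = 0.0432), at adjusted p = 0.301, 0.281, 0.367 and 0.236 with an estimated correlation. Median and mean differed in sign for rods (0.00031 and -0.017), cones (-0.014 and 0.0025) and the pigment epithelium (-0.029 and 0.21), none of them called (adjusted p = 0.468, 0.846 and 0.253). Greb1, an oestrogen-regulated gene of the sex steroid list, rose (0.59, SE 0.12, adjusted p = 0.0327). Medians by slide block (adjusted p in brackets), by slide 2 and by slide 4 follow. They were 0.076 (0.0119), 0.21 and 0.24 for bipolar cells, 0.11 (0.00269), 0.25 and 0.13 for endothelium and 0.084 (0.00232), 0.29 and 0.24 for visual cycle. The next were 0.041 (0.530), 0.13 and -0.0087 for unfolded protein response, -0.83 (1.61e-07), -0.19 and -1.83 for lens genes and -0.11 (0.0777), 0.029 and -0.19 for basement membrane. Then came 0.056 (0.589), 0.0083 and 0.010 for fibroblasts, -0.12 (0.00222), -0.15 and -0.10 for ganglion cells and -0.038 (0.0372), -0.048 and -0.020 for oxidative phosphorylation. The last were 0.032 (0.578), 0.11 and -0.051 for antioxidant defence and -0.045 (0.0309), -0.17 and -0.084 for cholesterol synthesis. The block ended the calls of unfolded protein response, basement membrane, fibroblasts and antioxidant defence. The sign within a slide was opposite for unfolded protein response on slide 4, basement membrane on slide 2, fibroblasts on slide 2, fibroblasts on slide 4 and antioxidant defence on slide 2. For single genes it ended those of Ly6a (0.95, adjusted p = 0.167), Atf3 (0.60, adjusted p = 0.0509), Col4a3 (0.82, adjusted p = 0.0907) and Greb1 (0.48, adjusted p = 0.248). When female young 1, 2, 3 or 4, female aged 1, 2, 3 or 4, male young 1, 2, 3 or 4 or male aged 1, 3 or 4 was left out, at least 1 of the calls named next ended. These were bipolar cells (adjusted p = 0.0776), endothelium (0.111), unfolded protein response (up to 0.197) and basement membrane (up to 0.326). Next came fibroblasts (up to 0.848), ganglion cells (up to 0.109), oxidative phosphorylation (up to 0.128) and antioxidant defence (up to 0.512). Others were cholesterol synthesis (up to 0.204), Ly6a (up to 0.173), Col4a3 (up to 0.0679) and Greb1 (up to 0.117). Without female young 4 the medians of fibroblasts and antioxidant defence were 0.083 and 0.023.

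The same comparison was made in males. Rgr, an opsin-like receptor gene of the pigment epithelium and Müller glia, rose 6.39-fold from 8.22 ± 0.82 to 10.90 ± 0.37 (2.68, SE 0.41, adjusted p = 0.00307, n = 4 each). Rpe65, the isomerase gene of the visual cycle in the pigment epithelium, rose 3.44-fold from 5.52 ± 0.38 to 7.30 ± 0.32 (1.78, SE 0.25, adjusted p = 0.00131). Slc16a8, a lactate transporter gene of the same cells, rose 3.16-fold (1.66, SE 0.32, adjusted p = 0.0176). The near-identical lysozyme genes Lyz1 (2.32, SE 0.51, adjusted p = 0.0373) and Lyz2 (2.31, SE 0.49, adjusted p = 0.0297) rose 5.0-fold and 4.97-fold. The paraoxonase gene Pon1 rose from 5.23 ± 0.50 to 7.43 ± 0.26 (2.20, SE 0.28, adjusted p = 0.000672). In all 115 probes (99 genes) rose and 34 (34 genes) fell. An unadjusted p under 0.05 was found for 2186, where chance gives 750.8. The basement membrane gene Tinag (2.13, SE 0.38, adjusted p = 0.00983), Trf (2.10, SE 0.22, adjusted p = 5.54e-05), Csrp3 (1.87, SE 0.15, adjusted p = 7.73e-06) and Edn2 (1.84, SE 0.33, adjusted p = 0.00983) completed the 10 largest rises. Dynlrb2 was at least 1.56-fold lower in aged males (5.22 ± 0.15 in young and 4.34 ± 0.08 in aged, adjusted p = 0.00244). The manganese transporter gene Slc30a10 fell from 5.52 ± 0.17 to 4.87 ± 0.17 (-0.65, SE 0.10, adjusted p = 0.00342). The histone gene H2ac7 (-0.56), Nxnl2 (-0.53), Spatc1l (-0.53), Vmo1 (-0.51), Bmp15 (-0.48), the mannosyltransferase gene Pomt2 (-0.47), Rasl11a (-0.45) and the kinase gene Stk36 (-0.45) fell too. These 8 had SEs of 0.08 to 0.13 and adjusted p-values of 0.00307 to 0.0478. Within slide 3, with 2 arrays of each age, all 149 called probes kept their sign, and within slide 1, with 1 of each, 147 did. The 10 rises ran from 0.63 (Tinag) to 2.73 (Rgr) on slide 1 and from 1.17 (Edn2) to 3.10 (Lyz2) on slide 3. A slide block gave 152 called probes, and the 10 rises ran from 1.68 for Slc16a8 to 2.65 for Rgr. It ended the calls of H2ac7 (-0.56, adjusted p = 0.0899), Spatc1l (-0.49, adjusted p = 0.0722), Vmo1 (-0.49, adjusted p = 0.0645), Pomt2 (-0.48, adjusted p = 0.0571) and Rasl11a (-0.47, adjusted p = 0.0645). The 149 calls became 92, 61 and 80 without male young 2, 3 and 4, 81 and 55 without male aged 2 and 3, and 230 without male aged 1, the array of disputed age. Runs without female young 1, 3 or 4, female aged 1, 2, 3 or 4, male young 1, 2, 3 or 4 or male aged 2, 3 or 4 ended at least 1 of the calls named next. These were Lyz1 (adjusted p up to 0.111), Lyz2 (up to 0.109), Tinag (0.0519) and Edn2 (0.0519). Next came Slc16a8 (up to 0.0776), H2ac7 (up to 0.156), Spatc1l (up to 0.115) and Vmo1 (up to 0.156). Others were Bmp15 (up to 0.0999), Pomt2 (up to 0.125), Rasl11a (up to 0.126) and Stk36 (up to 0.0672).

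Pigment epithelium genes, visual cycle genes and immune genes were called upward as lists in aged males. Of the pigment epithelium and melanocyte genes 4 of 12 rose and 0 fell (6 and 1 adjusted over the list alone), Rgr, Rpe65, the retinol acyltransferase gene Lrat (1.27, SE 0.24, adjusted p = 0.0139) and the retinol dehydrogenase gene Rdh5 (1.48, SE 0.32, adjusted p = 0.0347). The pigment epithelium list had a median log2 change of 0.27 (adjusted p = 0.000892, and adjusted p = 0.308 with an estimated correlation). Of the visual cycle genes, 5 of which are also in that list, 5 of 16 rose and 0 fell (9 and 2 adjusted over the list alone), the same 4 and Stra6, the receptor gene of retinol-binding protein (1.18, SE 0.18, adjusted p = 0.00342). The visual cycle list had a median log2 change of 0.25 (adjusted p = 6.69e-06, and adjusted p = 0.127 with an estimated correlation). Of the microglia and macrophage markers 10 of 21 rose (15 adjusted over the list alone). The microglia list had a median log2 change of 0.44 (adjusted p = 2.09e-18, and adjusted p = 0.00881 with an estimated correlation). The risen markers included Ly86 (0.57, SE 0.08, adjusted p = 0.00251), the growth factor receptor gene Csf1r (0.42, SE 0.08), the microglial receptor gene Trem2 (0.91, SE 0.18) and Cd52 (0.43, SE 0.09). Of the complement genes 2 of 13 rose (6 adjusted over the list alone), C1qb (0.89, SE 0.19) and C1qc (0.86, SE 0.18). The complement list had a median log2 change of 0.24 (adjusted p = 0.000234, and adjusted p = 0.134 with an estimated correlation), while C1qa (0.40, SE 0.15, adjusted p = 0.219), C3 (0.44, SE 0.15, adjusted p = 0.194) and C4b (0.88, SE 0.29, adjusted p = 0.169) did not pass. Of the interferon response genes 1 of 30 rose (12 adjusted over the list alone), Trim30a, at least 1.29-fold higher. The interferon list had a median log2 change of 0.28 (adjusted p = 2.88e-08, and adjusted p = 0.127 with an estimated correlation). The 3 blood genes, too few to test, had a median of 0.43 (0.047 within slide 1 and 0.57 within slide 3). The medians with slide as a block (adjusted p in brackets), within slide 1 and within slide 3 were these. They were 0.27 (0.00525), 0.17 and 0.60 for pigment epithelium, 0.26 (4.62e-05), 0.40 and 0.20 for visual cycle and 0.45 (5.52e-17), 0.43 and 0.46 for microglia. The next were 0.29 (6.63e-05), 0.084 and 0.20 for complement and 0.28 (1.28e-07), 0.17 and 0.25 for interferon response. For single genes the block ended the call of Trim30a (0.59, adjusted p = 0.0569). Leaving out male young 1, 2, 3 or 4 or male aged 1, 2, 3 or 4 ended at least 1 of the calls named next. These were Lrat (adjusted p up to 0.0640), Rdh5 (up to 0.141), Csf1r (up to 0.0540) and Trem2 (up to 0.0589). Next came Cd52 (up to 0.0684), C1qb (up to 0.103), C1qc (up to 0.0967) and Trim30a (up to 0.101).

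Further lists were called in males, and none of these calls held with an estimated correlation. Of the MHC class I genes 1 of 17 rose (6 adjusted over the list alone), the peptide transporter gene Tap2 (0.58, SE 0.13, adjusted p = 0.0373), and of the MHC class II genes 1 of 6 rose (1 adjusted over the list alone), the protease gene Ctss (0.49, SE 0.11, adjusted p = 0.0426), also a microglial marker. Of the cytokine and inflammasome genes 2 of 15 rose (4 adjusted over the list alone). They were Ccl12 (0.60, SE 0.12) and the caspase gene Casp1 (0.54, SE 0.10). Of the gliosis genes 2 of 18 rose (4 adjusted over the list alone), Edn2 and Osmr (0.80, SE 0.11, adjusted p = 0.00103). Gfap, near background, did not pass (-0.05, SE 0.09, adjusted p = 0.858). The 4 lists had median 0.26, adjusted p = 1.79e-05, median 0.15, adjusted p = 0.0400, median 0.13, adjusted p = 0.00564 and median 0.24, adjusted p = 0.00110, and adjusted p = 0.134, 0.308, 0.308 and 0.308 with an estimated correlation. Of the 64 ribosomal protein genes 56 lay above 0, 0 called singly (5 adjusted over the list alone). The ribosomal list had a median log2 change of 0.16 (adjusted p = 1.51e-11, and adjusted p = 0.134 with an estimated correlation). The cone photoreceptor list was called downward with 0 of 15 genes called singly (1 adjusted over the list alone) and a median log2 change of -0.15 (adjusted p = 0.0487, and adjusted p = 0.308 with an estimated correlation). Col4a3 rose (1.09, SE 0.17, adjusted p = 0.00312), as did the cell cycle inhibitor genes Cdkn2b (1.47, SE 0.27, adjusted p = 0.0133) and Cdkn1a (1.18, SE 0.24, adjusted p = 0.0239) of the senescence list, whose own test did not pass (median -0.0058, adjusted p = 0.0893). Male aged 1 lay at 5.87 for Cdkn2b and 5.41 for Cdkn1a, the other aged males at 7.05 to 7.20 and 6.29 to 6.52, and within slide 1, with that array, the changes were 0.31 and 0.015 (slide 3, 1.91 and 1.74). Median and mean differed in sign for bipolar cells (-0.035 and 0.043), lens genes (0.24 and -0.060) and senescence (-0.0058 and 0.24). List medians are given next with slide as a block (adjusted p in brackets), within slide 1 and within slide 3. They were 0.25 (4.62e-05), 0.17 and 0.18 for MHC class I, 0.17 (0.0487), -0.0026 and 0.14 for MHC class II and 0.18 (0.00257), 0.052 and 0.027 for cytokines. The next were 0.29 (0.000944), -0.064 and 0.40 for gliosis, 0.15 (3.45e-09), -0.047 and 0.22 for ribosomal proteins and -0.13 (0.0504), 0.039 and -0.23 for cones. The block ended the call of cones. Within slide 1, with male aged 1, the sign was opposite for MHC class II, gliosis, ribosomal proteins and cones. For single genes it ended those of Tap2 (0.57, adjusted p = 0.0639) and Ctss (0.44, adjusted p = 0.0645). The removal of female young 1 or 3, female aged 1, 2, 3 or 4, male young 1, 2, 3 or 4 or male aged 1, 2, 3 or 4 ended at least 1 of the calls named next. These were MHC class II (adjusted p up to 0.249), cytokines (0.0768), cones (up to 0.140) and Tap2 (up to 0.125). Next came Ctss (up to 0.108), Ccl12 (up to 0.0921), Casp1 (up to 0.0608) and Cdkn2b (up to 0.0600). Another was Cdkn1a (up to 0.0997).

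The mean of both aging effects asked which genes changed with age over the sexes together, with 8 arrays at each age. Crygb, a gamma crystallin gene of the lens, fell by 3.57 (SE 0.63, adjusted p = 0.00358), from 9.20 ± 0.87 to 5.75 ± 1.69 in females and from 9.63 ± 2.07 to 5.93 ± 0.99 in males. The largest rises were those of Rgr (2.22, SE 0.29, adjusted p = 0.000233), Lyz1 (2.02, SE 0.36, adjusted p = 0.00455), Lyz2 (1.94, SE 0.35) and Edn2 (1.93, SE 0.23, adjusted p = 0.000109). In all 210 probes (182 genes) rose and 72 (68 genes) fell. An unadjusted p under 0.05 was found for 1660. Trf (1.81), Csrp3 (1.74), Pon1 (1.65), Ccl21b (1.51), Rdh9 (1.45) and Ttr, the carrier of thyroxine and of retinol-binding protein (1.62), rose with SEs of 0.11 to 0.33 and adjusted p-values of 1.02e-07 to 0.0137. After Crygb the largest falls were those of Erdr1 (-2.07, SE 0.49, adjusted p = 0.0377), Crygn (-1.42, SE 0.22, adjusted p = 0.00117), 1110017D15Rik (-1.25, SE 0.27), the cyclin gene Ccnd2 (-1.04, SE 0.22, adjusted p = 0.0161) and Dynlrb2 (adjusted p = 5.86e-06), a bound in each sex. The microfibril gene Mfap4 (-0.86, SE 0.17), the anion exchanger gene Slc26a4 (-0.86, SE 0.18), Mid1 (-0.72, SE 0.14) and Crhbp, the binding protein of corticotropin-releasing hormone (-0.69, SE 0.15), fell as well. A slide block gave 275 called probes, and the 10 rises ran from 1.46 for Rdh9 to 2.36 for Rgr. It ended the calls of Erdr1 (-1.77, adjusted p = 0.0708) and Mid1 (-0.68, adjusted p = 0.0545). No slide held both ages of both sexes, so there is no value within a slide for this mean. When female young 1, 3 or 4, female aged 3, male young 2, 3 or 4 or male aged 1, 2, 3 or 4 was left out, at least 1 of the calls named next ended. These were Erdr1 (adjusted p up to 0.0892), 1110017D15Rik (0.0528) and Crhbp (up to 0.0532).

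Over both sexes 5 lists were called upward with an estimated correlation too. Of the microglia and macrophage markers 13 of 21 rose (19 adjusted over the list alone), Ly86 (0.66, SE 0.06, adjusted p = 4.78e-06), Cd14 (0.67, SE 0.09) and Trem2 (0.85, SE 0.13) among them. The microglia list had a median log2 change of 0.38 (adjusted p = 2.17e-29, and adjusted p = 0.00105 with an estimated correlation). Of the interferon response genes 10 of 30 rose (21 adjusted over the list alone), Trim30a, Parp14 (0.51, SE 0.07), Gbp2 (0.80, SE 0.12) and Oasl2 (0.79, SE 0.12) among them. The interferon list had a median log2 change of 0.34 (adjusted p = 2.12e-24, and adjusted p = 0.00347 with an estimated correlation). Of the complement genes 5 of 13 rose (7 adjusted over the list alone), C1qc (0.90, SE 0.12), C1qb (0.91, SE 0.13), C1qa (0.56, SE 0.11), C3 (0.49, SE 0.11, adjusted p = 0.0215) and C4b (0.94, SE 0.20, adjusted p = 0.0190). The complement list had a median log2 change of 0.26 (adjusted p = 1.50e-07, and adjusted p = 0.0396 with an estimated correlation). Of the MHC class I genes 5 of 17 rose (6 adjusted over the list alone), H2-T23 (0.45, SE 0.07) and Tap2 (0.46, SE 0.09) among them. The MHC class I list had a median log2 change of 0.15 (adjusted p = 1.47e-07, and adjusted p = 0.0396 with an estimated correlation). Of the visual cycle genes 6 of 16 rose and 0 fell (9 and 1 adjusted over the list alone), Rpe65 (1.27, SE 0.17), Stra6 (0.85, SE 0.13) and Lrat (0.98, SE 0.17) among them. The visual cycle list had a median log2 change of 0.19 (adjusted p = 3.84e-07, and adjusted p = 0.0396 with an estimated correlation). Beside these lists the median of the 3 blood genes, which were not tested as a list, was 0.84, and none of the 3 was called. Medians with slide as a block, with adjusted p in brackets, were 0.37 (1.25e-26) for microglia, 0.34 (7.05e-25) for interferon response, 0.36 (2.46e-09) for complement, 0.15 (4.17e-09) for MHC class I and 0.16 (5.29e-06) for visual cycle. Runs without female young 1, female aged 3, male young 2 or male aged 4 ended at least 1 of the calls named next. These were C3 (adjusted p up to 0.0533) and C4b (0.0507). None of these lists lost its call without any 1 array.

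The other 8 called lists lost their calls with an estimated correlation. Upward were the pigment epithelium (median 0.041, adjusted p = 0.00456), MHC class II (median 0.13, adjusted p = 0.0290), cytokines and inflammasome (median 0.10, adjusted p = 8.30e-05), reactive gliosis (median 0.11, adjusted p = 2.55e-05), ribosomal proteins (median 0.073, adjusted p = 6.65e-06) and the unfolded protein response (median 0.036, adjusted p = 0.0442), at adjusted p = 0.426, 0.331, 0.171, 0.229, 0.331 and 0.247 with an estimated correlation in that order. Of the pigment epithelium genes 5 of 12 rose and 1 fell (6 and 3 adjusted over the list alone), Rgr, Rpe65, Lrat, Rdh5 (1.21, SE 0.23) and Ttr upward and Slc26a4 downward. Of the cytokine genes 3 of 15 rose (3 adjusted over the list alone), Casp1 (0.47, SE 0.07), Ccl12 (0.67, SE 0.08) and the adhesion molecule gene Icam1 (0.51, SE 0.12), and of the gliosis genes 5 of 18 rose and 1 fell (6 and 1 adjusted over the list alone), Osmr (0.75, SE 0.08) and Lcn2 (0.82, SE 0.16) among the risen. Gfap lay at 4.53 to 4.60 in the 4 groups (adjusted p = 0.994), too near background to exclude a change. Of MHC class II 1 of 6 rose (1 adjusted over the list alone), Ctss (0.38, SE 0.08), of the unfolded protein response 1 of 27 rose (1 adjusted over the list alone), Atf3 (0.47, SE 0.07), and of the ribosomal proteins 0 of 64 rose (0 adjusted over the list alone). Downward were lens genes (median -0.23, adjusted p = 0.0107) and the basement membrane (median -0.21, adjusted p = 0.0458), at adjusted p = 0.581 and 0.581 with an estimated correlation. Of the lens genes 0 of 17 rose and 2 fell (1 and 4 adjusted over the list alone), Crygb and Crygn, and of the basement membrane genes 1 of 18 rose and 0 fell (1 and 5 adjusted over the list alone), with Col4a3 rising (1.00, SE 0.12, adjusted p = 0.000105). Medians with slide as a block, with adjusted p in brackets, were 0.52 (0.000246) for pigment epithelium, 0.11 (0.0145) for MHC class II, 0.10 (1.94e-05) for cytokines, 0.26 (6.20e-06) for gliosis and 0.069 (2.72e-06) for ribosomal proteins. The next were 0.020 (0.214) for unfolded protein response, -0.23 (0.0142) for lens genes and -0.13 (0.130) for basement membrane. The block ended the calls of the unfolded protein response and the basement membrane and that of Icam1 (0.49, adjusted p = 0.140). The pigment epithelium median turned to -0.023, -0.018 and -0.018 without female young 1, female aged 3 and male young 2, with the test still upward. Leaving out each of the 16 arrays in turn ended at least 1 of the calls named next. These were MHC class II (adjusted p up to 0.10), unfolded protein response (up to 0.102), lens genes (up to 0.150) and basement membrane (up to 0.244). Another was Icam1 (up to 0.0885).

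Photoreceptor, neuronal and Müller glia lists did not pass the test over both sexes, and limma called 0 of their members for the mean aging effect or for aging in either sex. Their medians, with adjusted p in brackets, were -0.048 (0.139) for rods, -0.084 (0.139) for cones, 0.036 (0.180) for bipolar cells, 0.0084 (0.403) for amacrine and horizontal cells, -0.088 (0.101) for ganglion cells and 0.020 (0.977) for Müller glia. Those of the other cell lists were 0.008 (0.0848) for endothelium, -0.080 (0.643) for skeletal muscle and -0.073 (0.0663) for fibroblasts. Those of functional lists were 0.081 (0.0875) for senescence, -0.016 (0.637) for oxidative phosphorylation, 0.0058 (0.637) for proteasome, 0.012 (0.944) for antioxidant defence and -0.029 (0.810) for immediate early genes. The remaining ones were 0.032 (0.637) for circadian clock, -0.0091 (0.810) for synaptic transmission, -0.033 (0.139) for cholesterol synthesis, -0.0099 (0.810) for sex steroid genes and 0.092 (0.180) for Y-linked and X-escape genes. Blood, with 3 measured genes, and lymphocytes, with 1, were too few to test, and their medians were 0.84 and 0.071. Within these lists Cdkn1a (0.98, SE 0.17, adjusted p = 0.00318), Cdkn2b (1.00, SE 0.19, adjusted p = 0.00891), Ly6a (0.72, SE 0.13, adjusted p = 0.00619) and Greb1 (0.42, SE 0.09, adjusted p = 0.0168) rose and Pdgfra fell (-0.69, SE 0.12, adjusted p = 0.00336). The slide block ended the call of Greb1 (0.36, adjusted p = 0.0708). Median and mean differed in sign for Müller glia, antioxidant defence and the sex steroid genes (means -0.010, -0.00071 and 0.010), and for immediate early genes the test was upward with a mean of -0.013.

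The overlap of the calls and the interaction address whether both sexes changed alike with age. Of the probes that rose, 41 (35 genes, among them Edn2, Trf, Csrp3, Osmr and Ly86) were called in both sexes, where independent lists would share 0.613 (Fisher's exact test, one-sided, p = 4.68e-68). Of those that fell, 4 were (Dynlrb2, Nxnl2, Bmp15 and Rasl11a), against 0.0340 (same exact test, p = 2.94e-08). Both lists share the probe variances and probes are not independent, so these p-values are too low. Of the 95 probes called in females 93 had the same sign in males and 83 also an unadjusted p under 0.05 there, and of the 149 called in males 136 and 91 did so in females. Across all 15016 probes the changes of both sexes had Pearson's r = 0.29 and Spearman's rho = 0.0049. Permuting the age labels within sex 100 times gave r from -0.42 to 0.35. With slide as a block 31 and 5 probes were shared and r was 0.33. Without male aged 3 the shared rises were 27, and without male aged 3 or 4 the shared falls were 2.

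**Figure D1:**
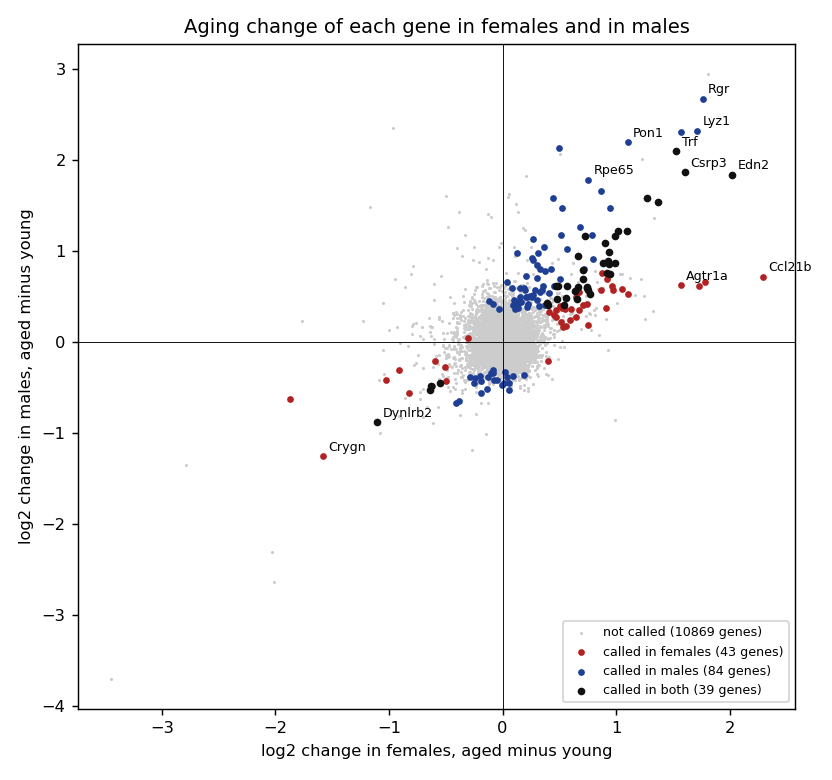
Aging change (log2, aged minus young) in females on the horizontal axis and in males on the vertical axis, 1 point per gene, coloured by whether the gene was called in both sexes, in 1 sex or in neither. Genes called in both sexes lie on the same side of 0 on both axes, Edn2 at 2.02 and 1.84 and Trf at 1.53 and 2.10.

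**Figure D2:**
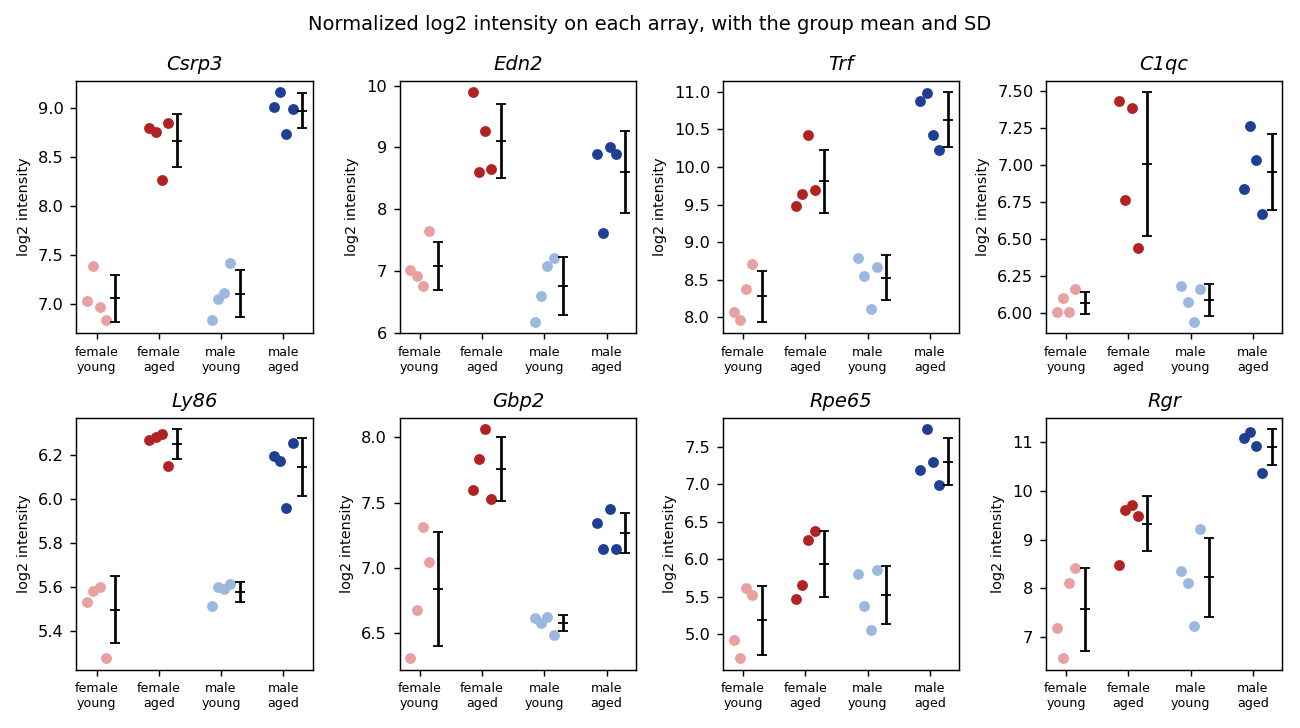
Log2 normalised intensity of 8 genes on each of the 16 arrays (points), by sex and age, with the mean and SD of each group (n = 4). Edn2 lies at means of 7.08 in young and 9.10 in aged females, and Rpe65 at 7.30 in aged males and 5.94 in aged females.

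The interaction asked whether the aging change of a gene differed between the sexes, as the change in males minus that in females. No probe passed the threshold (0 of 15016 with limma, and 0 with slide as a block or without any 1 array), while 1402 had an unadjusted p under 0.05 where chance gives 750.8. The smallest adjusted p was 0.289, for the protocadherin gene Pcdhga2 (-0.61, SE 0.11). The next values on the lower side were -0.68 for Crip3 (SE 0.15), -0.57 for Ash1l (SE 0.12) and -0.55 for Cdk12 (SE 0.12), and on the upper side 0.76 for Cmbl (SE 0.16), 0.57 for Rb1 (SE 0.13) and 0.42 for Pdlim2 (SE 0.11), all not past the threshold at an adjusted p of 0.456. Agtr1a, Slc7a10 and Txnrd1 stood at that adjusted p too, but no size is given, as each was detected on no array of 1 group or more. By list, camera made 9 calls, all lost with an estimated correlation, at adjusted p = 0.473 each, and the rotation test fry called 0 lists. The calls were 0.97 for lens genes (adjusted p = 3.87e-06), 0.66 for the pigment epithelium (0.0174), 0.20 for ribosomal proteins (1.29e-09), 0.20 for antioxidant defence (0.00703), 0.10 for the proteasome (0.0270) and 0.040 for oxidative phosphorylation (0.0245) as median differences upward. The differences of the melanin genes Tyrp1, Dct and Mlana of the pigment epithelium list were 0.82, 0.72 and 0.80, none past the threshold (picked after their values were seen). Downward it called -0.21 for the interferon response (0.00703), -0.12 for synaptic transmission (0.00703) and -0.17 for bipolar cells (0.0174), and the untested median of the 3 blood genes was -0.65. Adjusted over the list alone 1 member of antioxidant defence passed upward and 1 of bipolar cells and 1 of the interferon response downward. Medians with slide as a block, with adjusted p in brackets, were 1.26 (8.39e-05) for lens genes, 0.058 (0.690) for pigment epithelium, 0.17 (5.10e-05) for ribosomal proteins, 0.078 (0.111) for antioxidant defence and 0.071 (0.142) for proteasome. The next were 0.058 (0.0560) for oxidative phosphorylation, -0.24 (0.000124) for interferon response, -0.13 (0.103) for synaptic transmission and -0.15 (0.0230) for bipolar cells. The block ended 5 of the 9 calls. The removal of female young 1, 2 or 4, female aged 1, 2 or 4, male young 1, 2 or 4 or male aged 2 or 4 ended at least 1 of the calls named next. These were pigment epithelium (adjusted p up to 0.333), antioxidant defence (up to 0.0634), proteasome (up to 0.125) and oxidative phosphorylation (up to 0.153). Next came interferon response (up to 0.125), synaptic transmission (0.0634) and bipolar cells (up to 0.0921).

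The sexes were compared at each age, first at 3 months, with changes given as male minus female. Xist, the RNA that coats the inactive X chromosome, was at least 12.0-fold lower in males (4.36 ± 0.06 in males and 8.20 ± 0.32 in females, n = 4 each, limma adjusted p = 2.39e-12). The Y-linked genes Eif2s3y, of a translation factor, and Kdm5d, of a histone demethylase, were at least 19.0-fold and 2.66-fold higher in males (adjusted p = 1.40e-14 and 7.95e-09), and all 16 arrays lay on the side of their sex label for these 3 genes. Among autosomal genes, Vti1b of vesicle fusion (-1.33, SE 0.22, adjusted p = 0.00836), Trappc3 of vesicle tethering (-1.23, SE 0.16, adjusted p = 0.000864), the chromatin remodelling gene Nfrkb (-1.22, SE 0.12, adjusted p = 4.05e-05) and the glycosylation gene Alg8 (-1.03, SE 0.13, adjusted p = 0.000871) were lower in males, and the chemokine gene copies Ccl21b (1.36, SE 0.27, adjusted p = 0.0323) and Ccl21a (1.06, SE 0.19, adjusted p = 0.0152) were higher. In all 12 probes (12 genes) were higher and 47 (39 genes) lower in males, 2349 had an unadjusted p under 0.05, and 41 of the called genes were autosomal (8 higher, 33 lower). The clathrin adaptor gene Ap2b1 (-1.08), the lectin gene Clec2d (-1.04), the Notch target gene Hes5 (-0.97), Arl6ip5 (-0.85) and Samd7 of the rod list (-0.78) were lower too, with SEs of 0.11 to 0.19. Nrxn2, a gene of synaptic adhesion (0.70, SE 0.10, adjusted p = 0.00205), Dgkq (0.50, SE 0.10), Doc2g (0.50, SE 0.10) and Lime1 (0.41, SE 0.08) were higher. Of the 10 Y-linked and X-escape genes 4 were higher and 4 lower (4 and 6 adjusted over the list alone). These included the Y-linked Uty (0.59, SE 0.11, adjusted p = 0.0232) and Ddx3y (0.82, SE 0.17, adjusted p = 0.0404), whose probe was bright in females too (9.93 ± 0.36), and the X-linked Eif2s3x (-0.96, SE 0.11, adjusted p = 0.000254), Pbdc1 (-0.70, SE 0.09, adjusted p = 0.00107) and Kdm6a (-0.61, SE 0.09, adjusted p = 0.00246), while Kdm5c (-0.28, SE 0.09, adjusted p = 0.146) and Ddx3x (-0.75, SE 0.23, adjusted p = 0.143) did not pass. Their median of -0.44 and mean of 0.064 differ in sign, and the list was not called (adjusted p = 0.253). Median and mean differed in sign for ganglion cells (0.014 and -0.034) and cytokines (0.029 and -0.0013) too, and for complement the test was downward with a median of 0.022. None of the 32 lists was called by camera or fry, and the smallest camera adjusted p was 0.0507, for the proteasome (median -0.061). Within slides 2 and 3 all 59 called probes kept their sign. The named autosomal genes lower in males ran there from -1.10 for Ap2b1 to -0.54 for Arl6ip5 on slide 2 and from -1.48 for Vti1b to -0.69 for Ap2b1 on slide 3. A slide block left 26 called probes. It ended the calls of Vti1b (-1.33, adjusted p = 0.111), Ap2b1 (-1.10, adjusted p = 0.117), Clec2d (-0.99, adjusted p = 0.108), Dgkq (0.45, adjusted p = 0.186), Doc2g (0.44, adjusted p = 0.192) and Lime1 (0.35, adjusted p = 0.163). The 59 calls became 39, 91, 24 and 36 without female young 1, 2, 3 and 4, 30, 236, 32 and 27 without male young 1, 2, 3 and 4, and 108 without female aged 2. When female young 1, 2, 3 or 4, female aged 1, male young 1, 3 or 4 or male aged 1 or 3 was left out, at least 1 of the calls named next ended. These were Ap2b1 (adjusted p = 0.0633), Clec2d (up to 0.0587), Ccl21b (up to 0.116) and Ccl21a (up to 0.0718). Next came Ddx3y (up to 0.135), Uty (up to 0.0925), Dgkq (up to 0.129), Doc2g (up to 0.156) and Lime1 (up to 0.129).

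At 24 months Xist was at least 14.6-fold lower in males (4.45 ± 0.05 in males and 8.44 ± 0.19 in females), and Eif2s3y and Kdm5d were at least 21.1-fold and 2.91-fold higher (adjusted p = 9.16e-13, 6.83e-15 and 3.17e-09). Pon1 was higher in aged males (7.43 ± 0.26 in males and 5.81 ± 0.59 in females, 1.62, SE 0.28, adjusted p = 0.0140), and so was Rpe65 (7.30 ± 0.32 and 5.94 ± 0.45, 1.37, SE 0.25, adjusted p = 0.0165). The melanin genes Tyrp1 (1.70, SE 0.85), Dct (1.55, SE 0.79) and Mlana (1.68, SE 0.89) of the pigment epithelium list, picked after their values were seen, lay higher in aged males but did not pass the threshold (adjusted p = 0.429, 0.435 and 0.454). Lower in males, as at the young age, were Trappc3 (-1.27, SE 0.16, adjusted p = 0.00062), Vti1b (-1.26, SE 0.22, adjusted p = 0.0133), Nfrkb (-1.12, SE 0.12, adjusted p = 0.000147), Ap2b1 (-1.09, SE 0.19, adjusted p = 0.0140) and Alg8 (-1.12, SE 0.13, adjusted p = 0.000426), 1 of whose 3 probes had the opposite sign. The chaperone gene Dnajc7 (-1.16, SE 0.17, adjusted p = 0.00243), Zfp316 (-1.09, SE 0.14, adjusted p = 0.00128) and Metrn (-1.0, SE 0.19, adjusted p = 0.0183) were lower as well. In all 21 probes (21 genes) were higher and 82 (67 genes) lower in males, 1911 had an unadjusted p under 0.05, and 78 of the called genes were autosomal (18 higher, 60 lower). Rbm3, a cold-induced RNA-binding protein gene, was higher in males by the probe named here (1.03, SE 0.19, adjusted p = 0.0165), while only 1 of its 3 probes had that sign. The protease gene Adamts18 (0.98), Stra6 (0.92), the death receptor gene Tnfrsf10b (0.88), the chloride channel gene Clic6 (0.88) and Tmem98 (0.84) were higher with SEs of 0.18 to 0.21 and adjusted p-values of 0.0296 to 0.0495. Of the Y-linked and X-escape genes 2 were higher and 5 lower (4 and 5 adjusted over the list alone), with a median of -0.44 and a mean of 0.093. The X-linked Kdm5c (-0.68, SE 0.09, adjusted p = 0.00085), Kdm6a (-0.64, SE 0.09, adjusted p = 0.00156), Eif2s3x (-0.59, SE 0.11) and Pbdc1 (-0.51, SE 0.09) were lower, while Ddx3x (-0.37, SE 0.23, adjusted p = 0.547), Ddx3y (0.62, SE 0.17, adjusted p = 0.117) and Uty (0.43, SE 0.11, adjusted p = 0.0963) did not pass. Within slides 1 and 4 all 103 called probes kept their sign. The named genes higher in males, Y-linked ones aside, ran there from 0.19 for Adamts18 to 2.08 for Pon1 on slide 1 and from 0.53 for Clic6 to 1.46 for Adamts18 on slide 4. A slide block left 33 called probes. It ended the calls of Vti1b (-1.30, adjusted p = 0.0693), Ap2b1 (-1.20, adjusted p = 0.0506), Metrn (-1.09, adjusted p = 0.0648), Pon1 (1.62, adjusted p = 0.0608), Rpe65 (1.34, adjusted p = 0.0639), Rbm3 (0.97, adjusted p = 0.0553), Adamts18 (0.99, adjusted p = 0.0888), Stra6 (0.94, adjusted p = 0.0580), Tnfrsf10b (0.71, adjusted p = 0.123), Tmem98 (0.86, adjusted p = 0.0693), Pbdc1 (-0.43, adjusted p = 0.0561) and Eif2s3x (-0.50, adjusted p = 0.0693). The 103 calls became 28, 281, 26 and 37 without female aged 1, 2, 3 and 4, and 208, 37, 29 and 35 without male aged 1, 2, 3 and 4. Runs without female young 1, 2 or 3, female aged 1, 3 or 4, male young 1, 2, 3 or 4 or male aged 1, 2, 3 or 4 ended at least 1 of the calls named next. These were Vti1b (adjusted p up to 0.0641), Ap2b1 (up to 0.0639), Metrn (up to 0.0874) and Pon1 (0.0513). Next came Rpe65 (up to 0.0755), Rbm3 (up to 0.0674), Adamts18 (up to 0.164) and Stra6 (up to 0.118). Others were Tnfrsf10b (up to 0.124), Clic6 (up to 0.176), Tmem98 (up to 0.189) and Pbdc1 (up to 0.0792). Then came Eif2s3x (up to 0.0658).

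Camera called 11 lists for sex at 24 months, and none of these calls held with an estimated correlation. All 12 pigment epithelium and melanocyte genes and all 17 lens genes lay higher in aged males, 1 and 0 of them called singly (5 and 0 adjusted over the list alone), with median 1.26, adjusted p = 7.21e-08 and median 0.76, adjusted p = 4.92e-06, at adjusted p = 0.176 and 0.530 with an estimated correlation. Of the visual cycle genes 2 of 16 were higher and 0 lower (6 and 1 adjusted over the list alone), Rpe65 and Stra6. The visual cycle list had a median log2 change of 0.16 (adjusted p = 0.00543, and adjusted p = 0.473 with an estimated correlation). Higher in males with 0 members called singly were the basement membrane (median 0.37, adjusted p = 0.000116), fibroblasts (median 0.22, adjusted p = 0.0180), ribosomal proteins (median 0.13, adjusted p = 2.09e-07) and antioxidant defence (median 0.12, adjusted p = 0.0313), at adjusted p = 0.530, 0.593, 0.473 and 0.551 with an estimated correlation, and adjusted over the list alone 1 basement membrane gene passed and 0 of the others did. Of the interferon response genes 2 of 30 were lower in males (8 adjusted over the list alone), the ubiquitin-like gene Isg15 (-0.75, SE 0.12, adjusted p = 0.00531) and the transcription factor gene Irf9 (-0.45, SE 0.09, adjusted p = 0.0265). The interferon list had a median log2 change of -0.19 (adjusted p = 2.09e-07, and adjusted p = 0.176 with an estimated correlation). The median of the 3 blood genes, not tested, was -0.57 (-1.19 within slide 1 and 1.66 within slide 4). Of the rod genes 1 of 27 was lower, Samd7 (-0.69, SE 0.11, adjusted p = 0.00639), and of the unfolded protein response genes 1 of 27, the asparagine synthetase gene Asns (-0.50, SE 0.11, adjusted p = 0.0385), with 1 and 4 adjusted over the list alone. Rods (median -0.13, adjusted p = 0.000833), the unfolded protein response (median -0.088, adjusted p = 0.00490) and synaptic transmission (median -0.064, adjusted p = 0.0210, 0 of 35 called and 2 adjusted over the list alone) were called downward, at adjusted p = 0.530, 0.176 and 0.593 with an estimated correlation. Among lists that were not called, median and mean differed in sign for complement (-0.10 and 0.028), MHC class I (0.013 and -0.0088), cytokines (0.0086 and -0.013), gliosis (-0.0023 and 0.056) and the sex steroid genes (-0.022 and 0.026). With the slide as a block (adjusted p in brackets), within slide 1 and within slide 4, the medians were as follows. They were 1.22 (6.25e-07), 0.98 and 0.62 for pigment epithelium, 0.99 (9.29e-06), -0.13 and 1.80 for lens genes and 0.45 (2.07e-05), 0.090 and 0.51 for basement membrane. The next were 0.23 (0.00729), 0.12 and 0.22 for fibroblasts, 0.11 (9.29e-06), -0.058 and 0.22 for ribosomal proteins and 0.14 (0.0128), 0.35 and -0.035 for visual cycle. Then came 0.13 (0.0128), 0.011 and 0.13 for antioxidant defence, -0.22 (6.25e-07), -0.21 and -0.21 for interferon response and -0.10 (0.0474), 0.019 and -0.083 for rods. The last were -0.062 (0.0551), -0.12 and -0.081 for unfolded protein response and -0.070 (0.0128), 0.032 and -0.17 for synaptic transmission. The block ended the call of unfolded protein response. The sign was opposite for visual cycle on slide 4. On slide 1, whose only aged male was of disputed age, it was for lens genes, ribosomal proteins, rods and synaptic transmission. For single genes the block ended those of Irf9 (-0.38, adjusted p = 0.106), Asns (-0.43, adjusted p = 0.156) and Samd7 (-0.66, adjusted p = 0.0504). Leaving out female young 2, female aged 1, 2, 3 or 4, male young 1 or 3 or male aged 2, 3 or 4 ended at least 1 of the calls named next. These were fibroblasts (adjusted p up to 0.141), antioxidant defence (up to 0.283), synaptic transmission (up to 0.152) and Irf9 (up to 0.103). Another was Asns (up to 0.133).

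The autosomal probes called for sex at both ages were counted after the data had been seen. Of those lower in males 20 probes of 14 genes, among them Alg8, Nfrkb, Trappc3, Vti1b and Ap2b1, were called at both ages, where independent lists would share 0.202 (Fisher's exact test, one-sided, p = 7.05e-37). Of those higher 1 was (Nrxn2), against 0.0102 (same exact test, p = 0.0102). Both lists share the probe variances and probes are not independent, so these p-values are too low. Over 14102 autosomal probes the sex differences at both ages had r = 0.26 and rho = 0.20. With slide as a block 5 of the probes lower in males were shared. The 20 became 13 without female young 3 or male young 4, 6, 47, 7 and 11 without female aged 1, 2, 3 and 4, and 10, 9 and 9 without male aged 2, 3 and 4.

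**Figure D3:**
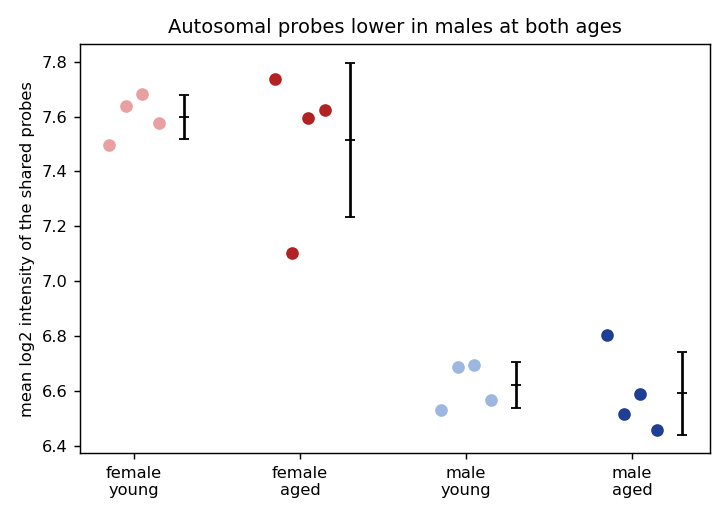
Mean log2 intensity of the 20 autosomal probes picked on these arrays as lower in males at both ages, 1 point per array, by sex and age, with group means and SDs (n = 4). Females lie at 7.10 to 7.74 and males at 6.46 to 6.80.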

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

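The 3 tests on the probes higher in females at both ages, both tests on the pigment epithelium genes and that of male aged 1 over probes called in males were chosen after the results were seen. An SE beside a median in this part is that of the change in the mean over the same probes or genes, from the spread between arrays.

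A single array lay far from the other 3 of its group for 28 of 488 groups of 4 tested over the named genes, where chance gives 24.4 (about 1 in 20), and for 10 of 128 over the lists, where chance gives 6.4. The value in brackets is the gap of that array to its nearest neighbour as a share of the range of the group. Array female young 1 stood apart for Eif2s3x (0.888) and Crip3 (0.830). On female young 2 these were Erdr1 (0.890) and the ribosomal list (0.932). On female young 3 it was Bmp15 (0.852). Array female young 4 stood apart for Lyz1 (0.924), Slc26a4 (0.886), Adamts18 (0.937), Clic6 (0.884), the pigment epithelium list (0.908), the MHC class II list (0.955) and the gliosis list (0.880). On female aged 1 these were Slc7a10 (0.944) and the ganglion cell list (0.973). With female aged 2 came Nfrkb (0.874), Metrn (0.953), Asns (0.911) and the rod list (0.877). Array female aged 3 stood apart for Csrp3 (0.842), Ly6a (0.947), Vmo1 (0.891) and the MHC class I list (0.844). On female aged 4 these were Nxnl2 (0.864) and the basement membrane list (0.974). With male young 1 came Irf9 (0.867), the cone list (0.862) and the lens list (0.901). On male young 3 it was Chia1 (0.832). On male young 4 these were Ccl21c (0.855), Slc30a10 (0.950) and Lime1 (0.901). With male aged 1 came Bmp15 (0.907) and Cdkn2b (0.886). Array male aged 2 stood apart for Edn2 (0.912) and Lyz2 (0.918). On male aged 3 these were Rbm3 (0.954) and Dgkq (0.939). On male aged 4 it was Ctss (0.858).

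In the test of the interaction camera called 9 lists, none of them with an estimated correlation (adjusted p = 0.473) and 5 no longer with slide as a block, which also takes out female young 4. The median log2 differences of males minus females were 0.97 for lens genes, 0.66 for the pigment epithelium (0.058 with the block), 0.20 for ribosomal proteins, 0.20 for antioxidant defence, 0.10 for the proteasome and 0.040 for oxidative phosphorylation. Below 0 lay -0.21 for the interferon response, -0.17 for bipolar cells and -0.12 for synaptic transmission.

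The 20 autosomal probes (14 genes) lower in males at both ages were picked on these arrays, which favours large changes. Their median male minus female change was -0.97 (SE 0.0851), or -0.94 (SE 0.117) with slide as a block, which argues against the slide. Female aged 2 (mean level 7.10) lay between the other females (7.50 to 7.74) and the males (6.46 to 6.80). The other 13 tested probes of 7 of these genes had a median of -0.27 (SE 0.0282), 11 of them lower in males at both ages. Single probes that bind another transcript may add to the size and cannot be told apart from a change of the genes. Of these genes 5 had more than 1 shared probe. The labels held 0 columns on sample preparation, so a preparation that followed sex cannot be told apart from sex. A biological difference between the sexes stays open and untested.

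The pigment epithelium genes Rpe65, Ttr, Lrat, Rgr, Rdh5 and Rrh, picked after their values were seen, had a median mean-aging change of 1.24 (SE 0.213), while the whole list of 12, with the melanin genes and Slc26a4 (-0.86), had 0.041. If pigmented tissue carried over in the dissection were the source, the change would shrink with the mean of the melanin genes Tyrp1, Dct and Mlana as a covariate. That mean changed by -0.15 (SE 0.70), or 0.40 (SE 0.46) without female young 4, so its sign decides nothing. This mean differs too little with age to shrink a change, so carry-over stays open. With the covariate the median was 1.27 (SE 0.204), or 1.28 (SE 0.226) without that array. With slide as a block it was 1.37 (SE 0.257), which argues against the slide. These tests cover the mean aging change alone. Carry-over also stays open for the higher pigment epithelium genes of aged males against aged females, where melanin genes differed the same way. So does an untested change with age in the retina or its pigment epithelium.

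Over the 95 probes called for aging in females, male aged 1, whose labels disagree on its age, lay 0.656 from the young male mean on the log2 scale. The other aged males lay at 0.614 to 0.679 and the young males at -0.0205 to 0.0304. As a share of the other aged males' mean distance this was 1.02, which argues against a young male labelled as aged and, for these probes, against an animal partway through the aging change. Over the 230 probes called in males without it the share was 0.555, against 0.834 to 1.01 for the other aged males left out the same way, and it lay at 5.87 for Cdkn2b where they lay at 7.05 to 7.20, so a change partway in these probes cannot be told apart from variation of 1 animal. An animal of 12 months stays open, since no array of a known 12-month animal was at hand.

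Called probes were counted for other splits of the same arrays into groups of equal size. For aging in females the real split gave 95 probes and the highest of the other splits 0 (1 of 35 reached 95). In males they were 149 and 58 (1 of 35) and for the mean of both 282 and 46 (1 of 100). No other split reached these, but so few splits cannot exclude chance. For sex at 3 months the real split gave 59 and another 87 (2 of 35), that of female young 1, 2 and 3 with male young 2. For sex at 24 months the values were 103 and 208 (2 of 35), with female aged 1, 3 and 4 and male aged 1 on 1 side. Chance cannot be excluded for the number of sex calls. The split at 3 months has both arrays of slide 2 on 1 side and parts slide 3, and that at 24 months parts slides 1 and 4, and with slide as a block the real counts were 26 and 33. For the interaction the real count was 0, which each of the 100 splits drawn reaches (highest 110), so that this count decides nothing there.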

How the results depend on the processing

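The alternatives for the autosomal probes called for sex at both ages were chosen after the data had been seen. Over all alternatives the 187 named calls of genes kept their direction, 94 kept their side of the threshold everywhere, and 87 lost it in a processing alternative and 80 with an array left out. Of the 61 list calls 8 were lost nowhere and 53 in a processing alternative, and 1 turned, that of fibroblasts in females, at -0.16 to 0.083 over the runs that leave out 1 array. With slide as a block the medians of fibroblasts and antioxidant defence in females changed sign (0.056 and 0.032) while the test did not, as did that of the pigment epithelium over both sexes without a filter (-0.028) or with the stricter one (-0.063). With an estimated correlation 8 list calls were left and fry gave 19. Called probes were counted again with each choice changed, and values over 1.5 times off follow, where the cause was not tested unless named. Median scaling gave 89 for males, 95.5% of them higher in place of 77.2%, and 2 shared falls. Without the filter females had 62, sex at 3 months 34, sex at 24 months 45, the shared rises 27 and the shared sex probes 8, with more probes to adjust over. The stricter filter, with fewer probes tested, gave 97 for males and 186 for the mean of both. With 1 probe per gene sex at 3 months had 37 and the shared sex probes were 13, again with fewer probes tested. Array weights gave 412 for males (58.7% higher), 187 and 233 for sex at 3 and 24 months (34.8% and 31.3% higher in males in place of 20.3% and 20.4%), 7 shared falls and 44 shared sex probes. Slide as a fixed block gave 26 and 33 for sex at both ages and 5 shared sex probes, and as a random block 8 shared falls, while camera takes no random block and gave no value there. Slide 1 against the others gave 37 for sex at 3 months and 7 shared falls. With only the 2 groups compared, fewer arrays, females had 36 and sex at 24 months 28. An unadjusted p under 0.05 with a fold of 1.2 gave 641 in females, 1299 in males, 553 for the mean, 1409 and 1152 for sex and 1277 for the interaction. Over the runs without 1 array, females had 59 to 99 calls, males 55 to 230, the mean 212 to 315, sex at 3 months 24 to 236, sex at 24 months 26 to 281 and the interaction 0 throughout. The shared rises were 27 to 46, the shared falls 2 to 5, the shared sex probes 6 to 47, the list calls 52 to 71 and r 0.17 to 0.38. Under all choices the median change of all probes lay between -0.0282 and 0.0258.

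The replicate numbers share only a number, since the deviations of arrays with the same number correlated at -0.34 to 0.38 (mean -0.054, other numbers 0.018) and 1 of 16 arrays correlated best with its own number. With the number as a block males had 79 calls and sex at 3 and 24 months 36 and 55. Beyond the values given in this part, no choice moved a count by over 1.5 times. Arrays of the same slide correlated at a mean of 0.094 and of different slides at -0.023. Signal over background limits what can be seen, as 52.6% to 57.0% of the probes were detected per array.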

Other observations

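This part gives values alone, with no test. Genes of pigmented cells varied widely between arrays of 1 group. Tyrp1, an enzyme gene of melanin synthesis, lay at 6.01 to 10.67 in young females, 5.87 to 7.73 in aged females, 6.80 to 9.50 in young males and 7.38 to 9.89 in aged males, highest in female young 4. Dct and Mlana had their highest values, 11.87 and 10.21, on that array too, and their lowest, 6.82 and 5.07, on female young 3.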
